A study of Mus musculus with 8 samples.

How the data were processed

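The data are RNA-seq counts from laser-captured tissue of mouse hearts, in 8 libraries. GFP-positive tissue (labelled Purkinje) and GFP-negative background tissue were cut from unfixed frozen sections of 10 µm, and total RNA was prepared with a kit for small samples, per the labels' protocols. The deposited table holds raw counts per gene symbol, and the counts were used as deposited; the authors' processing notes name the aligner STAR, the genome build mm10 and DESeq2, per the submitters' processing notes, with no versions. The annotation, the counting program and the strandedness are not given in the sources used here, so reads of a gene and an overlapping antisense gene cannot be told apart, and reads of near-identical copies may be split. The table lists 19328 symbols, none with a total below 16 counts over the 8 libraries. Of these 95.7% matched GENCODE M21 (GRCm38, the assembly of mm10), from which coordinates were taken. The table holds 23 symbols altered to dates, of which 2 repeat an earlier symbol, and these were not named.

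Libraries were grouped by their titles into 4 groups of 2. The total count was 32069400 to 35770900 per library. TMM factors were 1.18 to 1.22 in Purkinje and 0.774 to 0.877 in background libraries. To look for a library deposited more than once, the counts of each replicate pair were compared. All pairs differed by more than sampling noise (chi-square per gene of 6.12 to 14.9 over genes with at least 50 counts in the pair), so none was merged. This does not show that replicates came from separate animals. Intervals of ratios of counts are exact binomial (Clopper-Pearson) at 95% and cover counting error only, since PCR copies are not independent molecules. A fold against a group with 0 counts was computed against a floor of 3 counts over the group.

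Counts were filtered with filterByExpr, which kept 16495 genes and removed 2833, and scaled by TMM. A model with 1 mean per group over all 8 libraries was fitted with edgeR 4.0.16 (quasi-likelihood F test, robust) in R 4.3.3. Contrasts were Purkinje against background (mean of sham and LAD, in sham, in LAD), LAD against sham in each region, and the interaction. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and adjusted p-values of single genes are from this fit. Standard errors were derived from the F statistic. Gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 37 lists with at least 5 tested members in each of 4 comparisons; of 38 lists fixed, the adipocyte list had 3 tested members and was not tested. The lists cover conduction, working myocardium, contraction, channels, metabolism, matrix, stress and signalling genes and markers of other cell types. Expected overlaps are n1 × n2 / N. The libraries of the comparisons set against each other are separate, but each gene has a spread shared by all groups. A gene with a small spread is easier to call in both, so the calls are not independent and the excess over the expected overlap can be overstated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

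The groups, comparisons, lists, tests and named-gene rule were fixed before the data were examined. The rule named the 8 genes with the largest rise and the 8 with the largest fall among called genes with non-overlapping libraries and a mean log2 CPM above the median (3.62), up to 4 members with the smallest p of each list described, a panel of 12 genes, and the 5 genes with the smallest p for the interaction. Where fewer than 4 members of a list, or fewer than all panel genes, are named, those were picked from the genes the rule gives after their values were seen. Which lists to describe was also settled then. Alternatives planned were DESeq2 size factors, no low-count filter, the DESeq2 1.42.0 Wald test, limma voom with quality weights, a fit of the compared groups alone, a replicate block, leaving out each library, an adjusted p under 0.1, and an estimated correlation for the lists. Library size alone, leaving out mitochondrially encoded genes, and the summed CPM of 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) as a covariate were added after seeing the data.

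The analysis was tested on simulated counts with the real scaled library sizes and 200 genes changed. Before that change each gene had its mean over all libraries in every group, so the real difference between the regions was absent. The false shares below therefore do not carry over to the calls from the real counts, above all those for region. With 1 spread for all groups, 16089 genes entered the Purkinje LAD step. Of genes changed 1.5-fold 56.9% were recovered, of those changed 2-fold 76.9% and of those changed 4-fold 96.9%. The false share was 6.83% of the calls of this step and 11.0% of those of the interaction. With each group's own spread the false share was 29.6% for LAD in Purkinje (16111 genes), 0.746% for LAD in background (16056 genes), 5.20% for region (16083 genes) and 8.27% for the interaction (16111 genes). Fits of the compared groups alone gave 12.2% and 9.64% for LAD in Purkinje (15936 genes) and in background (15255 genes). A camera run on simulated counts with 3 lists shifted 1.3-fold called all 3, and 2 of the 34 others. Genes were drawn independently of each other in these counts, so the run does not test the preset inter-gene correlation.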

Results

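Gene expression was measured by RNA-seq in 8 laser-captured samples from the hearts of Pitx2c-CreERT2/+;mTmG mice. In these animals an inducible Cre recombinase, driven from the Pitx2c locus, switches a reporter from red to green fluorescence (GFP). GFP-positive tissue, labelled as cardiac Purkinje cells (the ventricular end of the conduction system), and GFP-negative background tissue were captured from hearts at postnatal day 12. The hearts had undergone ligation of the left anterior descending coronary artery (LAD) or a sham operation 10 days earlier. The 4 groups, Purkinje LAD, Purkinje sham, background LAD and background sham, held 2 libraries each. Raw counts per gene summed to between 32069400 and 35770900 per library, and 18714 to 18993 genes had at least 1 count. The labels do not say whether the replicates came from separate animals, nor do they tie a capture to a heart. The 4 Y-linked genes had 1 count in Purkinje sham replicate 1 and 2822 in Purkinje sham replicate 2. That pair therefore did not hold the same set of animals. For the other pairs separate animals were not shown. The p-values therefore measure the spread between these samples, which may be technical, and are too small if captures shared an animal. Region separated the libraries on the first principal component, which held 68.7% of the variance, and LAD from sham separated on the second, which held 12.05%.

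The first question was how the captured Purkinje tissue differed from the background tissue. Genes of the conduction system were far higher in the Purkinje captures. Transcripts of Cntn2, the cell adhesion protein contactin 2 and a known Purkinje marker, averaged 689 ± 97.1 CPM (counts scaled by library size and TMM, SD, n = 4) against 8.09 ± 3.60 in background, a log2 fold change of 6.49 ± 0.20 (SE). Gja5, the gap junction protein connexin 40, averaged 136 ± 25.0 CPM against 12.4 ± 1.19 (SD, n = 4 each), 3.43 on the log2 scale. The pacemaker channel gene Hcn4 (log2 fold change 5.05), the transcription factor genes Etv1 (3.42) and Irx3 (0.72) and the cardiac sodium channel gene Scn5a (1.33) were also higher. Cntn2 lies on chromosome 1 at 132509427 to 132543256, Gja5 on chromosome 3 at 96904693 to 97077416 and Hcn4 on chromosome 9 at 58823412 to 58863175 (GENCODE M21, GRCm38, all protein-coding). Of the 28 conduction genes tested, 26 were higher and 0 lower (26 and 0 adjusted over the list alone), with a median log2 fold change of 2.10 (camera adjusted p = 1.36e-51, and 0.00685 with an estimated correlation). Neuronal adhesion and axon guidance genes were higher in 19 of 23 and lower in 1 (19 and 1 adjusted over the list alone), with a median of 1.82 (camera adjusted p = 4.90e-27, and 0.00824 with an estimated correlation). They included Slit3 (3.97), Ephb3 (3.87), Ncam1 (3.19) and Ntm (4.43). Cntn2, Ntm, Sema3a, Ephb3 and Slit2 stand in both lists.

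**Figure D1:**
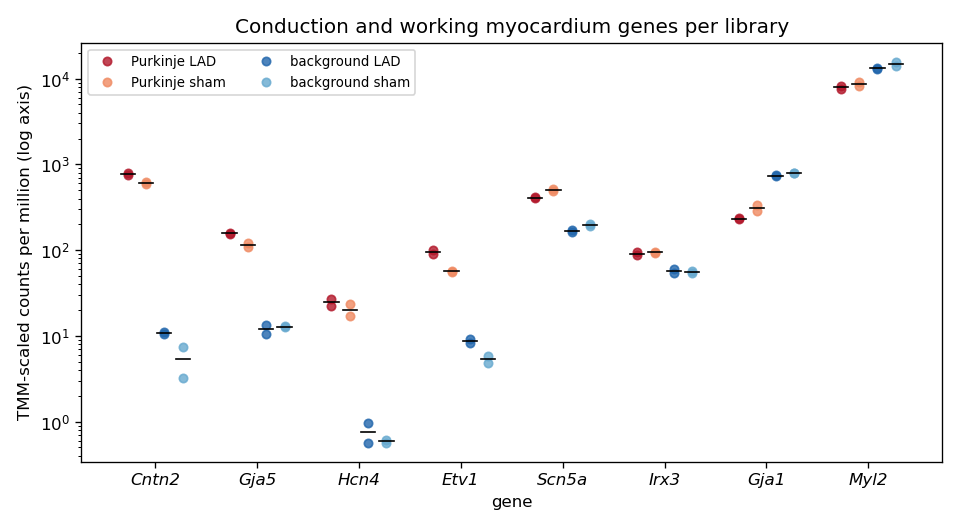
TMM-scaled CPM (log axis) of 8 genes in each of the 8 libraries. Each point is a library and each short line the mean of the 2 libraries of a group. Cntn2, Gja5, Hcn4, Etv1, Scn5a and Irx3 lie higher in every Purkinje library than in every background library, and Gja1 and Myl2 lie lower.

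The genes with the largest differences, among those called, with non-overlapping libraries and above the median expression, were led on the Purkinje side by Sbk3, which encodes a protein kinase (log2 fold change 6.75), Cntn2, the sodium channel gene Scn10a (5.53), Spock2 (5.31), the guidance factor gene Sema3a (4.48), Ntm, Stard10 (4.42) and Slit3. On the background side stood Myh11, the smooth muscle myosin heavy chain (-4.38), Murc (-2.99), Rbp7 (-2.98), the carbonic anhydrase gene Car4 (-2.97), Klhdc8a (-2.68), Ly6a (-2.65), Ptgds (-2.55) and the muscle fructose bisphosphatase gene Fbp2 (-2.53). Pitx2, whose locus drives the label, had 0 or 1 count in each Purkinje library. It had 19 and 25 counts in the background LAD libraries and 4 and 8 in the background sham libraries. Pooled over sham and LAD, the ratio of background to Purkinje was 40.3 (95% interval 10.6 to 341, counting error only), with most of the background counts from LAD.

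Genes of the working myocardium and of energy metabolism were mostly lower in the Purkinje captures. Of 17 working-myocardium genes, 11 were lower and 3 higher (11 and 3 adjusted over the list alone; camera adjusted p = 1.68e-06; adjusted p = 0.0691 with an estimated correlation). The transient outward current genes Kcnip2 (-1.76) and Kcnd2 (-2.80) and the connexin 43 gene Gja1 (-1.51) were lower, while Irx5, a transcription factor gene, was higher (2.09). The ventricular light chain gene Myl2 was also lower (-0.76). Sarcomere genes were lower in 14 of 16 (14 adjusted over the list alone; Myoz2 -1.01, Tnnc1 -1.09; camera adjusted p = 2.14e-06; adjusted p = 0.268 with an estimated correlation). Calcium handling genes were lower in 12 of 16 and higher in 2 (the same counts adjusted over the list alone), with Ryr2, the calcium release channel, at -1.35 (camera adjusted p = 0.000870; adjusted p = 0.0691 with an estimated correlation). In contrast, cardiac ion channel genes were higher in 15 of 27 and lower in 9 (also adjusted over the list alone), the T-type calcium channel genes Cacna1h (3.45) and Cacna1g (2.37) among the higher (camera adjusted p = 0.0105; adjusted p = 0.0987 with an estimated correlation).

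All 14 mitochondrially encoded transcripts tested were lower (14 adjusted over the list alone), with a median log2 fold change of -1.93 (camera adjusted p = 2.62e-19; adjusted p = 0.0966 with an estimated correlation). mt-Nd5 (-2.09) and mt-Nd2 (-2.03), both complex I subunits, had the smallest p. These transcripts made up 11.4% to 13.9% of counts in the Purkinje libraries and 28.2% to 32.9% in the background libraries. Singled out after their values were seen, mt-Nd3, mt-Atp8, mt-Atp6, mt-Co2 and mt-Co3 had only 50 to 498 counts each over the 8 libraries, against at least 1023270 for each of the other 9. The shares therefore hold almost no reads of these 5 genes; the median of the other 9 was -1.80. Whether reads were lost to near-identical nuclear copies was not tested, so single values are uncertain. Other measures of RNA composition moved with region too. Nuclear long noncoding RNAs were higher in Purkinje in 6 of 7 (6 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 0.0351; adjusted p = 0.346 with an estimated correlation). That call was lost with library size alone (0.0606) and without Purkinje LAD replicate 1 (0.0780) or 2 (0.0788), Purkinje sham replicate 2 (0.0516), background LAD replicate 1 (0.0697) or background sham replicate 2 (0.0501). Ribosomal protein genes were lower in 27 of 28 (27 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 3.47e-05; adjusted p = 0.512 with an estimated correlation), which was 0.15 with library size alone (0.0883). An 18S ribosomal RNA sequence held 0.236% to 0.296% of counts in the Purkinje libraries and 0.154% to 0.202% in the background libraries. All 28 nuclear genes of oxidative phosphorylation were lower, for example Cycs (-1.20) and Uqcrfs1 (-1.11), with 28 adjusted over the list alone and a median of -0.93 (camera adjusted p = 2.70e-20; adjusted p = 0.205 with an estimated correlation). Fatty acid oxidation genes were lower in 25 of 27 and higher in 1 (the same adjusted over the list alone), with Pdk4 (-2.49), Ucp3 (-1.95) and Hmgcs2 (-1.69) at the front (camera adjusted p = 3.50e-28; adjusted p = 0.0691 with an estimated correlation). Tricarboxylic acid cycle genes were lower in 16 of 16 (16 adjusted over the list alone; camera adjusted p = 5.60e-12; adjusted p = 0.228 with an estimated correlation).

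Markers of other cell types moved with region in different directions. Of 14 fibroblast genes, 13 were higher in Purkinje and 0 lower (13 and 0 adjusted over the list alone). Fbln1 (3.04), Gsn (1.87) and the receptor gene Pdgfra (1.44) were among them, and the median was 1.37 (camera adjusted p = 2.02e-22, and 0.00685 with an estimated correlation). Endocardial genes were higher in 12 of 14 and lower in 1 (12 and 1 adjusted over the list alone). Cytl1 (3.70), the natriuretic peptide receptor gene Npr3 (3.66) and Cgnl1 (2.42) were higher, and the median was 1.78 (camera adjusted p = 2.70e-20, and 0.00685 with an estimated correlation). Matrix and collagen genes were higher in 21 of 27 and lower in 5 (the same adjusted over the list alone), with Col1a1 (1.92), Col3a1 (1.89) and Postn (0.69) among the higher (camera adjusted p = 1.31e-13; adjusted p = 0.0691 with an estimated correlation). Smooth muscle and pericyte genes were lower in 11 of 14 (11 adjusted over the list alone), with Myh11, Rgs5 (-2.11) and Tagln (-1.95) (camera adjusted p = 1.81e-14; adjusted p = 0.0586 with an estimated correlation). Endothelial genes were lower in 11 of 16 and higher in 5 (the same adjusted over the list alone; camera adjusted p = 0.00937; adjusted p = 0.268 with an estimated correlation). Ly6c1 (-2.02), Cav1 (-1.49) and the VEGF receptor gene Kdr (-1.34) were lower and Eng (1.28) was higher. Of 11 epicardium and valve genes 7 were lower and 3 higher (the same adjusted over the list alone), with Wt1 at -2.27 and Aldh1a2 at 1.75 (camera adjusted p = 0.000745; adjusted p = 0.0691 with an estimated correlation). Cell cycle genes were lower in 26 of 26 (26 adjusted over the list alone), including Rrm2 (-1.61), Mki67 (-1.43) and Top2a (-1.36) (camera adjusted p = 5.35e-10; adjusted p = 0.0502 with an estimated correlation).

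Across all 16495 genes tested, 10738 differed between the regions on the mean of sham and LAD (edgeR quasi-likelihood, adjusted p under 0.05), 5406 higher and 5332 lower in Purkinje, and 2806 of them by at least 2-fold. In sham hearts alone 8917 genes differed and in LAD hearts alone 8847. Of the genes higher in Purkinje, 3597 were called in both (1192 expected for independent lists), and of those lower 3626 (1199 expected). The lists are not independent, since the fits share a spread per gene. Nppa, the atrial natriuretic peptide gene, did not pass the test (0.74, edgeR adjusted p = 0.0771), but did with the DESeq2 Wald test, voom quality weights, library size alone and the Y-linked covariate (adjusted p from 6.55e-06 to 0.0116). It also passed without Purkinje sham replicate 1 (0.44, edgeR adjusted p = 0.00884) or 2 (0.94, adjusted p = 0.000127). Nppb, which encodes the related B-type peptide, was lower (-2.32). The calls were 50.3% higher under TMM scaling and 87.3% higher with library size alone, a scaling chosen after the data were seen, which moved the median log2 fold change of all genes from 0.01 to 0.54. With that scaling the medians of the calcium handling, glycolysis, creatine and ketone, ribosomal protein, endothelial and hypoxia lists changed sign. This follows from the shift of all genes: each of the 6 stayed below the median of all genes (relative medians -0.49 to -0.25), though of these lists only creatine and ketone passed with that scaling (camera adjusted p = 0.00308).

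The second question was how the captured Purkinje tissue responded to coronary ligation. Casq1, the skeletal calsequestrin, rose from 17.7 ± 0.0803 to 57.3 ± 6.604 CPM (SD, n = 2 each), a log2 fold change of 1.70 ± 0.08 (SE). The genes with the largest rises by the fixed rule were, after Casq1, the matrix gene Hmcn2 (1.51), the angiotensin-converting enzyme gene Ace (1.41), the Slit receptor gene Robo1 (1.36), the interferon-induced gene Ifit2 (1.16), the thrombospondin gene Thbs1 (1.14), Ddc (1.10) and Pi16 (1.09). The largest falls were in Nr4a1, an immediate early transcription factor (-2.06), Art1 (-1.80), Ces1d (-1.42), Slc38a3 (-1.32), Asb15 (-1.26), Slc26a10 (-1.22), Igfbp3 (-1.15) and Asb14 (-1.13). Of the conduction genes, 9 of 28 rose and 3 fell (9 and 4 adjusted over the list alone), the median being 0.19 (camera adjusted p = 0.00296; adjusted p = 0.298 with an estimated correlation). Cacna2d2, a calcium channel subunit (1.70), the transcription factor genes Tbx3 (0.82) and Etv1 (0.73) and the connexin gene Gja5 (0.45) rose, and the pacemaker channel gene Hcn2 (-0.58) and Scn5a (-0.29) fell. Cntn2 (0.34, edgeR adjusted p = 0.323), Hcn4 (0.29, adjusted p = 0.174), Nppa (-0.55, adjusted p = 0.421) and Nppb (0.50, adjusted p = 0.377) did not pass. Gja1 (-0.41) and Kcnip2 (-0.74) of the working myocardium fell.

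Matrix genes rose in 17 of 27 in the Purkinje captures (18 adjusted over the list alone), among them Lum (0.56), Fn1 (0.52), Fbn1 (0.52) and Postn (0.27). Their median was 0.34 (camera adjusted p = 2.50e-11, adjusted p = 0.259 with an estimated correlation). Fibroblast genes rose in 5 of 14 and fell in 1 (6 and 3 adjusted over the list alone), with a median of 0.08. That list passed at the preset correlation (camera adjusted p = 0.0379). It did not pass with an estimated correlation (0.298) or with library size alone (0.0549). Cell cycle genes rose in 7 of 26 (12 adjusted over the list alone), for example Rrm2 (0.61), Cdk1 (0.61) and Top2a (0.51) (camera adjusted p = 2.69e-05; adjusted p = 0.259 with an estimated correlation). Smooth muscle genes rose in 5 of 14 and fell in 0 (5 and 1 adjusted over the list alone): Cnn1, calponin, by 2.97, Tagln by 0.99 and the actin gene Acta2 by 0.93 (camera adjusted p = 0.000401; adjusted p = 0.298 with an estimated correlation). Cardiac stress genes rose in 6 of 19 (6 adjusted over the list alone), including Nmrk2 (0.69), Uchl1 (0.60) and Rcan1 (0.38) (camera adjusted p = 0.000401; adjusted p = 0.393 with an estimated correlation). Neuronal adhesion genes rose in 7 of 23 and fell in 2 (7 and 4 adjusted over the list alone), with the semaphorin genes Sema3d at 1.13 and Sema3c at 0.60 (camera adjusted p = 0.00296; adjusted p = 0.259 with an estimated correlation). Immediate early genes fell in 7 of 18 (8 fell and 2 rose adjusted over the list alone), with Fos (-1.59) and Dusp1 (-0.87) beside Nr4a1 (camera adjusted p = 0.00157; adjusted p = 0.544 with an estimated correlation). Oxidative phosphorylation genes fell in 7 of 28 (16 adjusted over the list alone), such as Slc25a4 (-0.41) and Uqcrc1 (-0.33) (camera adjusted p = 4.25e-06; adjusted p = 0.544 with an estimated correlation). In contrast, mitochondrially encoded transcripts rose in 4 of 14 (4 adjusted over the list alone), mt-Nd2 by 0.61 and mt-Nd5 by 0.55 (camera adjusted p = 0.00629; adjusted p = 0.544 with an estimated correlation). Endothelial genes fell in 2 of 16 (2 adjusted over the list alone), Egfl7 (-0.73) and Cldn5 (-0.40) (camera adjusted p = 0.0243; adjusted p = 0.494 with an estimated correlation). Lymphocyte genes fell in 4 of 12 (4 adjusted over the list alone), from low levels: Cd8a averaged 2.19 ± 0.281 CPM in sham and 0.240 ± 0.168 in LAD (SD, n = 2 each), and Cd3e (-2.81) and Lck (-1.67) also fell (camera adjusted p = 0.00467; adjusted p = 0.259 with an estimated correlation).

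In total 2903 genes differed between LAD and sham in Purkinje (edgeR, adjusted p under 0.05), 1588 higher and 1315 lower in LAD. Of these 330 differed by at least 2-fold. At the preset correlation 19 of 37 lists passed, 10 up and 9 down, and with an estimated correlation 0 passed. The Purkinje replicates were more variable than the background ones (biological coefficient of variation 7.74% and 9.61% against 3.75% and 4.30%), and the model shares one spread. In counts simulated with each group's own spread and 200 genes changed, 29.6% of the calls of this comparison were false. A fit of the Purkinje libraries alone gave 12.2% there. A false share depends on how many genes change, so neither share carries over to the calls from the real counts. On the real counts the fit of the Purkinje libraries alone called 1909 genes, 1899 of them shared. In that fit the calls of Nr4a1 (edgeR adjusted p = 0.0572), Art1 (0.0528) and Postn (0.0551) were lost and Cntn2 passed (0.0114), and with voom quality weights Nppb passed (0.0208). Y-linked transcripts summed to 110 and 174 CPM in the LAD libraries and to 0.0262 and 66.0 CPM in the sham libraries, so the sexes were mixed unevenly. With that sum as a covariate, an alternative chosen after the data were seen, 371 genes and 12 lists passed, and of the 54 genes named here 21 lost their call. Cldn5, one of these, changed sign, as did Hcn4 and Nppa, which had not passed. The others lost were Thbs1, Nr4a1, Tbx3, Lum, Cdk1, Top2a, Fos, Gja1, Gja5, Scn5a, Postn, Slc25a4, Uqcrc1, Cd3e, Lck, Sema3c, mt-Nd2, mt-Nd5, Nmrk2 and Rcan1. Some kept log2 fold changes near those given above, such as mt-Nd2 (0.61 with the covariate), Nmrk2 (0.68) and Cd3e (-2.77). Others shrank, such as Lck (-0.85), Slc25a4 (-0.11) and Uqcrc1 (-0.014). With the covariate the oxidative phosphorylation, tricarboxylic acid cycle, fatty acid oxidation, glycolysis, sarcomere and ribosomal protein lists, all lower in LAD, turned direction. None of these lists had passed with an estimated correlation. The neuronal adhesion (camera adjusted p = 0.0765), endothelial (0.496), lymphocyte (0.121), atrial and fetal (0.0581) and Schwann and neuron (0.213) lists no longer passed. Without Purkinje LAD replicate 2, 1482 genes were called. Some calls depended on a single library: Postn on Purkinje LAD replicate 1 (edgeR adjusted p = 0.0886 without it), Slc25a4 and Lck on Purkinje LAD replicate 2 (0.0802 and 0.0717), and Uqcrc1 and Cldn5 on Purkinje LAD replicate 2 or Purkinje sham replicate 1 (0.0882 to 0.138 and 0.169 to 0.202). Without Purkinje sham replicate 1 the change of Nppa, which did not pass, turned to 0.041, and without Purkinje sham replicate 2 it passed (-0.97, edgeR adjusted p = 0.00576). Some genes passed when a library was left out: Cntn2 without background sham replicate 1 (0.00194) or 2 (0.00193), Hcn4 without Purkinje sham replicate 2 (0.00428) and Nppb without Purkinje sham replicate 1 (4.56e-06). The median of the conduction list was 0.107 without Purkinje LAD replicate 1 and 0.0234 without Purkinje sham replicate 2. That of immediate early genes turned from -0.202 to 0.039 without Purkinje sham replicate 1. The smooth muscle median was only 0.037, and it turned to -0.010 without Purkinje LAD replicate 2 and to -0.080 without Purkinje sham replicate 2. The camera direction of both lists stayed the same in these fits. Among the lists described, the call was lost without Purkinje LAD replicate 1 for immediate early genes and without Purkinje sham replicate 1 for endothelial genes. Without Purkinje sham replicate 2 it was lost for mitochondrially encoded transcripts, cardiac stress genes and fibroblast genes. Of the lists that turned, sarcomere, glycolysis and tricarboxylic acid cycle lost their call without Purkinje LAD replicate 2 (0.0625, 0.0967 and 0.0749). They did so without Purkinje sham replicate 1 as well (0.177, 0.256 and 0.679), as did fatty acid oxidation (0.332).

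The third question was how the background tissue responded. Skeletal actin, Acta1, rose from 13.1 ± 1.56 to 317 ± 3.54 CPM (SD, n = 2 each), a log2 fold change of 4.59. Thbs4, a thrombospondin, rose from 4.19 ± 0.0861 to 68.1 ± 5.60 CPM (SD, n = 2 each), a log2 fold change of 4.02. Nppa rose by 2.78 (edgeR adjusted p = 0.0297). The matrix list genes Tnc (2.26) and Thbs1 (1.42), and Sfrp2 (2.15), Ptn (2.03) and Abi3bp (1.40), completed the 8 largest rises by the fixed rule. The largest falls were smaller: Art1 (-1.37), Lgr6 (-1.22), Lgals4 (-1.22), Ces1d (-1.12), Slc36a2 (-1.04), Wnk2 (-0.99), Ttll1 (-0.98) and the muscle ribosomal protein gene Rpl3l (-0.96). Matrix and collagen genes rose in 24 of 27 (25 adjusted over the list alone), including Postn (1.34), Col5a2 (0.89) and Fn1 (0.78). Their median was 0.70 (camera adjusted p = 4.15e-67, and 0.0121 with an estimated correlation). Cell cycle genes rose in 25 of 26 (26 adjusted over the list alone), with Rrm2 (1.18), Top2a (0.91) and Cdk1 (0.90) and a median of 0.73 (camera adjusted p = 1.24e-36, and 0.0121 with an estimated correlation). Fibroblast genes rose in 11 of 14 (12 adjusted over the list alone), including Pdgfrl (1.26), Col1a2 (0.88), Lum (0.82) and Col1a1 (0.63) (camera adjusted p = 1.67e-17, and 0.0121 with an estimated correlation). Of the 14, 4 are also in the matrix list.

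Atrial and fetal cardiac genes rose in 5 of 13 in background (5 adjusted over the list alone), with Myl4, the atrial light chain (1.36), and Dkk3 (1.24) beside Acta1 and Nppa (camera adjusted p = 6.76e-11, and 0.0180 with an estimated correlation). Cardiac stress genes rose in 8 of 19 (11 adjusted over the list alone), with Nmrk2 (1.86), Xirp2 (1.33) and Uchl1 (1.32) (camera adjusted p = 4.32e-22, adjusted p = 0.0550 with an estimated correlation). The atrial and fetal list and the cardiac stress list had the same median (0.648), that of a gene in both. The lists overlap, so these are not separate results. The keratin genes Krt8 (3.01) and Krt18 (2.42) rose within the epicardium and valve list, of which 4 of 11 rose (4 adjusted over the list alone, camera adjusted p = 4.72e-07, and 0.0367 with an estimated correlation). Its members Wt1 (0.23, edgeR adjusted p = 0.324), Upk3b (0.06, adjusted p = 0.883) and Upk1b (0.39, adjusted p = 0.452) did not pass. The list result therefore does not show a rise of epicardial markers in general. Oxidative phosphorylation genes fell in 6 of 28 (21 adjusted over the list alone; Uqcrc1 -0.32, Cox4i1 -0.32; camera adjusted p = 3.21e-10; adjusted p = 0.468 with an estimated correlation). Mitochondrially encoded transcripts fell in 3 of 14 (3 adjusted over the list alone), the ribosomal RNA genes mt-Rnr1 (-0.47) and mt-Rnr2 (-0.41) among them (camera adjusted p = 0.00141; adjusted p = 0.476 with an estimated correlation). Ion channel genes fell in 8 of 27 and rose in 2 (11 and 2 adjusted over the list alone), with the potassium channel genes Kcnip2 (-0.44) and Kcnj2 (-0.44) and the sodium channel gene Scn5a (-0.22) lower (camera adjusted p = 0.000446; adjusted p = 0.0763 with an estimated correlation). Conduction genes rose in 7 of 28 and fell in 3 (7 and 5 adjusted over the list alone), with Etv1 at 0.72, and the list did not pass (camera adjusted p = 0.337; adjusted p = 0.610 with an estimated correlation). Cntn2 (1.01, edgeR adjusted p = 0.146), Nppb (0.93, adjusted p = 0.1795) and Gja5 (-0.10, adjusted p = 0.650) did not pass. Nppb passed with the DESeq2 Wald test (0.0440), with voom quality weights (1.05e-07) and with the background libraries alone (2.54e-20), and Cntn2 with voom (0.000171). Gja5 changed sign with library size alone, which also ended the calls of Scn5a (0.419), Uqcrc1 (0.0827) and Cox4i1 (0.0698) and of the neutrophil (camera adjusted p = 0.143) and smooth muscle (0.111) lists. At the preset correlation the neutrophil list had passed as higher (camera adjusted p = 0.0196) and the smooth muscle list as lower (0.0193). Neither passed with an estimated correlation (0.468 each). The neutrophil call also ended without background LAD replicate 2 or background sham replicate 1.

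In background 1515 genes differed between LAD and sham, 963 higher and 552 lower in LAD (63.6% higher, and 90.2% with library size alone, which shifted the median of all genes by 0.12). Of these 258 differed by at least 2-fold. At the preset correlation 18 of 37 lists passed, 9 up and 9 down, and with an estimated correlation 5 passed. A fit of the background libraries alone called 3306 genes, 1498 of them shared, so the order of the response counts of the 2 regions turned with that choice. Y-linked transcripts were higher in the LAD libraries here as well (141 and 129 CPM, against 88.9 and 89.6 in sham). With their sum as a covariate 1152 genes passed, 948 of them shared. The calls of Uqcrc1 (edgeR adjusted p = 0.153), Cox4i1 (0.181), mt-Rnr1 (0.0537) and mt-Rnr2 (0.0592) were lost, as were the sarcomere and the smooth muscle lists. These genes stayed lower in LAD with the covariate, with log2 fold changes of -0.19, -0.19, -0.41 and -0.35 in the same order. Without background LAD replicate 1 or 2 or background sham replicate 1 or 2, the count was 695, 677, 766 or 721. Leaving out any 1 of the 4 background libraries ended the calls of Nppa, Art1, Ces1d, Uqcrc1 and Scn5a (edgeR adjusted p up to 0.206, 0.152, 0.152, 0.117 and 0.340), and that of Nppa also ended without either Purkinje LAD library (0.0600 at least). The calls of Acta1 (0.0657 to 0.0753) and Lgals4 (0.0665 to 0.136) ended without either background sham library, and Lgals4 also without either Purkinje LAD library. Those of Cox4i1 (0.121 to 0.201) and mt-Rnr2 (0.0558 to 0.298) ended without background LAD replicate 1 or 2 or background sham replicate 2, and that of mt-Rnr1 (0.104 to 0.170) without background LAD replicate 1 or background sham replicate 2. Gja5 changed sign without background LAD replicate 2 (0.048). Cntn2 passed without background sham replicate 1 (0.0254) or 2 (4.00e-08), and Nppb without Purkinje sham replicate 1 (5.82e-08) or 2 (7.03e-08). The list of mitochondrially encoded transcripts did not pass without background LAD replicate 1 (camera adjusted p = 0.168) or background sham replicate 2 (0.0889).

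The fourth question was whether the response to ligation differed between the regions. Thbs4 rose in background and was 49.4 ± 2.33 CPM in Purkinje sham and 41.8 ± 0.771 in Purkinje LAD (SD, n = 2 each), giving an interaction of -4.26 ± 0.13 on the log2 scale (Purkinje response minus background response). Col11a1, a fibrillar collagen (-2.92), and Xirp2, an actin-binding protein of the intercalated disc (-1.33), also responded less in Purkinje. Pi16 (1.46) and Hmcn2 (2.06) had interactions of the other sign, and Pi16 rose in Purkinje from 37.6 ± 2.88 to 80.2 ± 1.17 CPM (SD, n = 2 each). These were the 5 genes with the smallest p (edgeR adjusted p from 2.48e-16 to 7.56e-08). Of the 27 matrix genes 9 had a lower response in Purkinje and 0 a higher one (15 and 1 adjusted over the list alone), including Tnc (-1.84), Postn (-1.08), Col1a2 (-0.84) and Col1a1 (-0.80). Their median was -0.28 (camera adjusted p = 2.67e-22; adjusted p = 0.0926 with an estimated correlation). Fibroblast genes showed 5 of 14 lower (7 adjusted over the list alone; Pdgfrl -1.59; camera adjusted p = 5.12e-10; adjusted p = 0.0773 with an estimated correlation), and cell cycle genes 3 of 26 lower (11 adjusted over the list alone; Bub1b -0.74, Ccna2 -0.62, Rrm2 -0.56; camera adjusted p = 2.36e-11; adjusted p = 0.0773 with an estimated correlation).

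**Figure D2:**
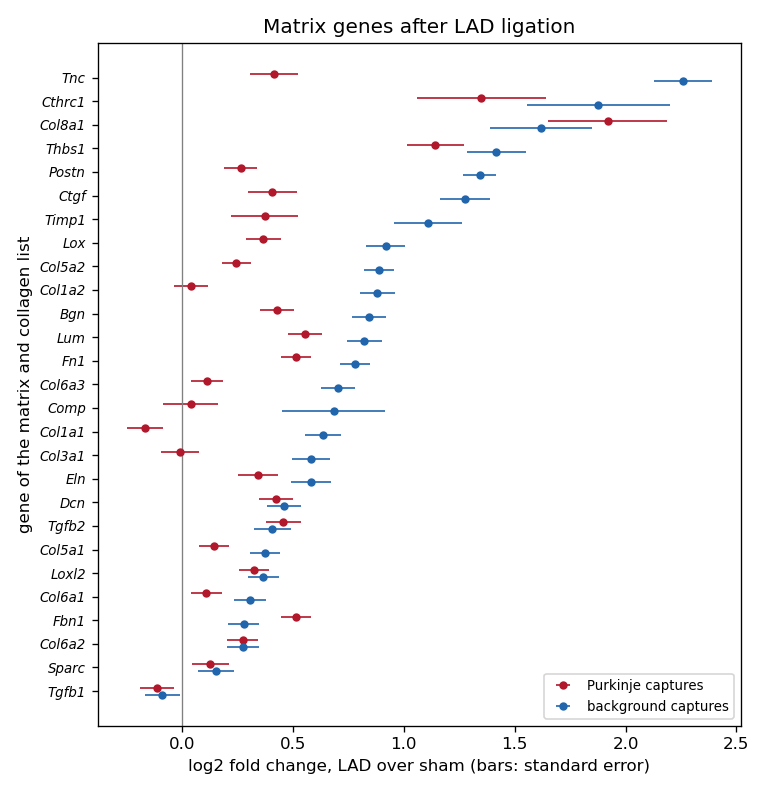
Log2 fold change of LAD over sham for the 27 genes of the matrix and collagen list, in Purkinje captures and in background captures; points are edgeR estimates from 2 libraries per group and bars are standard errors. Tnc (0.42 against 2.26) and Postn (0.27 against 1.34) lie further right in background.

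The smooth muscle genes Cnn1 (1.91), Tagln (1.16), Acta2 (1.12) and Mylk (0.73) had a higher response in Purkinje, 4 of the 14 of their list (5 adjusted over the list alone; camera adjusted p = 4.72e-11; adjusted p = 0.125 with an estimated correlation). Mitochondrially encoded transcripts did so in 2 of 14 (8 adjusted over the list alone; mt-Nd2 0.74, mt-Nd5 0.64; camera adjusted p = 2.36e-11; adjusted p = 0.294 with an estimated correlation). Cardiac stress genes had a lower response in 3 of 19, and in 5 adjusted over the list alone, where 1 was higher (Nmrk2 -1.17, Uchl1 -0.72; camera adjusted p = 4.93e-07; adjusted p = 0.294 with an estimated correlation). Atrial and fetal genes were lower in 2 of 13, and in 4 adjusted over the list alone, where 1 was higher (Myl4 -1.30, Dkk3 -0.76, camera adjusted p = 0.000899, adjusted p = 0.125 with an estimated correlation). This list overlaps the cardiac stress list. Immediate early genes passed as a list (camera adjusted p = 0.000190; adjusted p = 0.702 with an estimated correlation) with 0 of 18 called (5 lower and 1 higher adjusted over the list alone); Fos was at -1.20 and Dusp1 at -0.41. Lymphocyte genes had a lower response in 1 of 12, Cd8a (-3.08), and in 2 adjusted over the list alone (camera adjusted p = 0.0143; adjusted p = 0.250 with an estimated correlation). Of 28 conduction genes 4 had a higher and 2 a lower response in Purkinje (5 and 4 adjusted over the list alone). Tbx3 (0.95), Gja5 (0.55) and Rgs6 (0.42) were higher and Ephb3 (-0.61) was lower, and the list did not pass (camera adjusted p = 0.328; adjusted p = 0.782 with an estimated correlation). Nppa did not pass (-3.33, adjusted p = 0.127).

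In all 249 genes had a response that differed between the regions, 99 higher and 150 lower in Purkinje (39.8% higher, and 15.1% with library size alone, which shifted the median of all genes to -0.13). Calls of the separate comparisons overlapped, with 488 genes higher after ligation in both regions (92.7 expected for independent lists). Of the others, 314 were lower in both (44.0 expected) and 21 were called in opposite directions. Over all genes the Pearson correlation of the 2 responses was 0.294. The regions share a spread per gene in the model, so the lists are not independent and the excess can be overstated. Y-linked transcripts were higher in the LAD libraries of both regions, and the overlap does not separate sex composition from ligation. The interaction count was 124 without background LAD replicate 2, 145 without either background sham replicate and 445 without Purkinje sham replicate 2. Calls near the threshold were lost in many of the 8 fits that left out a library (edgeR adjusted p in brackets). Rrm2 (0.0832 to 0.299) was lost in 7, without any library but Purkinje sham replicate 2, and Ccna2 (0.0635 to 0.353) in 7, without any but Purkinje sham replicate 1. Bub1b (0.0546 to 0.366) was lost in 6, without any but Purkinje sham replicate 1 and background LAD replicate 2. Gja5 (0.0509 to 0.272) was lost in 5, without Purkinje LAD replicate 1, Purkinje sham replicate 1, background LAD replicate 2 or either background sham replicate. The mt-Nd5 call (0.0699 to 0.216) was lost in 5, without either replicate of Purkinje LAD or background LAD or without background sham replicate 2. Cd8a (0.0528 to 0.172) was lost in 4, without Purkinje LAD replicate 1, background LAD replicate 2 or either background sham replicate, and mt-Nd2 without background LAD replicate 1 (0.0829). Rgs6 (0.0550 to 0.0992) was lost without any of the 4 background libraries, and Ephb3 without background LAD replicate 1 (0.0513). Some genes passed when a library was left out: Fos and Dusp1 without Purkinje LAD replicate 2 (0.0453 and 0.0148) or Purkinje sham replicate 2 (0.00125 and 0.00836), and Nppa without Purkinje sham replicate 1 (0.00103) or 2 (0.000135). The lymphocyte list was lost without background LAD replicate 2 (camera adjusted p = 0.0624) and the immediate early list without Purkinje LAD replicate 1 (0.144). Other alternatives ended calls too (edgeR adjusted p unless a tool is named). Rgs6 (0.164) and Gja5 (0.118) were lost with library size alone, as was the lymphocyte list (camera adjusted p = 0.0809). Rrm2 and Ccna2 were lost with DESeq2 size factors (0.0561 and 0.0549), no low-count filter (0.0505 and 0.0520), mitochondrially encoded genes left out (0.0574 and 0.0585), the DESeq2 Wald test (0.104 and 0.103) and voom weights (0.106 and 0.0843). Bub1b was lost with the DESeq2 Wald test (0.0689). A replicate block ended the calls of Ccna2 (0.0571) and mt-Nd5 (0.0717). Of immediate early genes, Fos passed with the block (0.0325) and with library size alone (0.0303), and Dusp1 with library size alone (0.00833) and voom (0.0458). With the Y-linked covariate 272 genes passed, 184 of them shared; the calls of Gja5 (0.0661) and Rrm2 (0.213) and that of the lymphocyte list (camera adjusted p = 0.0842) were lost. Nppa passed with that covariate (0.000166), with the DESeq2 Wald test (2.45e-07) and with voom quality weights (9.98e-10).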

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

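The comparison of responses between the regions was planned; of the tests of explanations, all 3 of the mitochondrially encoded transcripts, both of the fibroblast and endocardial markers and those of other splits of the libraries were chosen only after the result was seen. No group held the 4 libraries needed to look for a single library apart from the rest, and every column of the deposited table was used.

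The response to ligation differed between Purkinje and background in 249 genes by the interaction test. The interactions on the log2 scale were -4.26 for Thbs4, 1.46 for Pi16, -1.33 for Xirp2, 2.06 for Hmcn2 and -2.92 for Col11a1. Among the lists that passed, median interactions were -0.28 for matrix and collagen, -0.22 for fibroblast, -0.39 for cell cycle, -0.27 for cardiac stress, -0.42 for immediate early, -0.21 for atrial and fetal cardiac, -0.28 for lymphocyte, -0.13 for ribosomal protein, 0.46 for mitochondrially encoded, 0.16 for smooth muscle and pericyte and 0.13 for interferon response genes, and none of the 11 passed with an estimated correlation. Of these medians 6 moved by over 1.5 times when 1 library was left out. The ribosomal protein list did not pass without Purkinje LAD replicate 2 (-0.0547), Purkinje sham replicate 1 (-0.0712), background LAD replicate 2 (-0.0833) or background sham replicate 1 (-0.0689), and its median was -0.213 without Purkinje LAD replicate 1. The interferon response list did not pass without Purkinje LAD replicate 1 (0.102), Purkinje sham replicate 1 (0.0606), background LAD replicate 1 (0.142) or background sham replicate 2 (0.149), nor with DESeq2 size factors (camera adjusted p = 0.0536) or mitochondrially encoded genes left out (0.0596), and its median was 0.218 without Purkinje sham replicate 2. The cardiac stress median was -0.0826 and -0.514 without Purkinje LAD replicate 1 and 2, -0.0739 and -0.453 without Purkinje sham replicate 1 and 2, and -0.132 without background LAD replicate 1. The atrial and fetal median was -0.141 without Purkinje LAD replicate 1, -0.0955 and -0.322 without Purkinje sham replicate 1 and 2, and -0.137 without background sham replicate 1. The lymphocyte median was -0.505 and -0.153 without Purkinje LAD replicate 1 and 2 and -0.179 without background sham replicate 1, and the list did not pass without background LAD replicate 2 (camera adjusted p = 0.0624). The immediate early median was -0.251 without Purkinje sham replicate 1, and the list did not pass without Purkinje LAD replicate 1 (camera adjusted p = 0.144).

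The matrix list had a lower response to ligation in the Purkinje captures at the preset correlation, with 9 of 27 genes called lower and 18 not called. It did not pass with an estimated correlation (adjusted p = 0.0926). With the Y-linked covariate, added after the data were seen, the matrix median of the interaction was -0.39, against -0.28 without it. The list still passed at the preset correlation (camera adjusted p = 1.01e-23), so the adjustment did not shrink the difference. It cannot exclude uneven sex composition, because the covariate is correlated with the LAD contrast and its slope rests on differences between replicates. A higher starting level with an equal absolute gain stays open for the list as a whole. Fewer CPM were gained in Purkinje by 18 of the 27 genes, short of the 20 set beforehand, and the rest gained more. The summed gain was 1922 CPM in Purkinje and 3923 CPM in background. Gains were not equal gene by gene. Col1a1 changed by -310 CPM in Purkinje and 312 in background, and Col3a1 by -48.4 and 783. In the other direction, Dcn gained 456 and 223 CPM and Sparc 367 and 245. A different response of the captured cells, or a different distance of the captured tissue from the injury, was not tested and also stays open.

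Mitochondrially encoded transcripts were lower in the Purkinje captures. Scaling alone is argued against, since the list median closest to 0 over the 3 scalings was -1.40. A smaller share of cardiomyocyte RNA as the whole cause is also argued against, because the list fell relative to sarcomere genes by a further 1.31 (value -1.31, mean difference -3.42 ± 0.283 in Purkinje and -2.11 ± 0.200 in background, SD, n = 4 libraries each). Over the 9 genes with many counts this was -1.16. A lower mitochondrial content is a candidate explanation, because nuclear oxidative phosphorylation genes also fell relative to sarcomere genes (-0.29, with every Purkinje library below every background library), though by much less. A larger nuclear share of the captured RNA, or a difference in RNA quality, also stays open: nuclear long noncoding RNAs were higher in 6 of 7 (camera adjusted p = 0.0351) and ribosomal protein genes lower in 27 of 28 (camera adjusted p = 3.47e-05), though neither passed with an estimated correlation (0.346 and 0.512) or with library size alone (0.0606 and 0.0883). Shared reads with nuclear copies were not tested.

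Fibroblast and endocardial markers were higher in the Purkinje captures. A smaller cardiomyocyte share that raises every other cell type alike is argued against, because the fibroblast median exceeded the smooth muscle median by 2.55 and smooth muscle and pericyte markers were lower. Fibroblasts and endocardial cells captured with the fibres cannot be told apart from expression of these genes by the labelled cells: 25 of the 28 markers were higher, which both would give, and the captures were chosen by GFP, so region and label coincide. The most abundant of the genes named for these lists, Col1a1, averaged 2672 ± 182 CPM in Purkinje and 720.3 ± 185 in background (SD, n = 4 each), and 4 of the 14 fibroblast genes are also in the matrix list. No sort removed other cell types.

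Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many genes as Purkinje against background. It called 9184 in a model with 2 groups, and the highest of the others gave 9. Each other split mixes the regions and so adds their difference to the spread, which keeps its count low. The counts of the other splits therefore do not show what chance alone would give, and they cannot exclude it. For the lists, 1 of the 35 splits gave as many as the real 23, but the highest of the others gave 22, so the number of lists past the threshold hardly sets the real split apart; the splits with 22 each hold 3 libraries of one region and 1 of the other.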

How the results depend on the processing

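Of the named genes, 61 of 62 for region, 28 of 54 for LAD in Purkinje, 32 of 45 for LAD in background and 19 of 31 for the interaction kept their direction and side of the threshold in every alternative. Of the lists called, 4 of 23, 0 of 19, 5 of 18 and 0 of 11 did so. Library size alone, leaving out mitochondrially encoded genes and the Y-linked covariate were chosen after seeing the data. The cause of the changes below was not tested, except that leaving out a library removes samples and that the covariate takes out part of the LAD contrast, with which it is correlated.

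The count of genes for LAD in Purkinje was 2903, and 1909 with only the groups compared, 1903 with voom quality weights and 371 with the Y-linked covariate. That for LAD in background was 1515, and 3306 and 2876 with the first 2 of these. With an estimated correlation the lists were 4 in place of 23 for region, 0 in place of 19 for LAD in Purkinje, 5 in place of 18 for LAD in background and 0 in place of 11 for the interaction; with the Y-linked covariate 12 lists passed for LAD in Purkinje.

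Leaving out each library in turn gave 9668 to 10835 genes for region, 6973 to 9156 in sham, 7116 to 9454 in LAD, 1482 to 3494 for LAD in Purkinje, 677 to 2101 for LAD in background and 124 to 445 for the interaction, and 22 to 25, 16 to 21, 18 to 20 and 9 to 14 lists for region, LAD in Purkinje, LAD in background and interaction. Where this left 1 library in a group, it was assumed to vary like the other groups.

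With the Y-linked covariate the LAD response in Purkinje changed sign for Hcn4 (-0.34), Nppa (0.74) and Cldn5 (0.15), and for the medians of the sarcomere (0.0909), oxidative phosphorylation (0.0384), fatty acid oxidation (0.0507), glycolysis (0.0996), tricarboxylic acid cycle (0.0803) and ribosomal protein (0.0631) lists, and of the endothelial list (0.0443), whose camera direction stayed down. For the interaction the ribosomal protein list changed direction (-0.00202). Leaving out each library gave -0.97 (without Purkinje sham replicate 2) to 0.041 (without Purkinje sham replicate 1) for Nppa in Purkinje and -0.29 (without background LAD replicate 1) to 0.048 (without background LAD replicate 2) for Gja5 in background, which was 0.021 with library size alone.

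Same-numbered libraries did not deviate together (correlations of deviations from the group means between -0.05 and 0.06), so the numbers were not taken to pair samples. A replicate block gave 10604, 8749, 8698, 2939, 1550 and 284 genes for region, region in sham, region in LAD, LAD in Purkinje, LAD in background and the interaction, each within 1.5 times the count without the block; for the interaction it ended the calls of Ccna2 and mt-Nd5 and let Fos pass. Alternatives for normalized values were not run, since the table holds counts. Genes with a few counts, such as Pitx2, are limited by depth.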

Other observations

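The gene groups below were chosen after seeing the data, and no explanation of them was tested. Transcripts of the mast cell proteases Cpa3, Cma1, Mcpt4 and Tpsb2 were nearly missing from the Purkinje sham captures, with 2 and 3 counts in all in the libraries, and reached 217 and 230 counts in the Purkinje LAD libraries. The ratio of LAD to sham was 87.3 (95% interval 37.1 to 270, counting error only). In background the same genes summed to 367 and 346 counts after ligation and 338 and 336 after sham, a ratio of 0.913 (0.821 to 1.02). Kit and Hdc, which other cells also express, did not follow. Kit had 458 and 445 counts in the Purkinje sham libraries and 509 and 541 in the Purkinje LAD libraries, a change that did not pass (log2 fold change 0.18, edgeR adjusted p = 0.285). In background, where the proteases hardly changed, Kit rose after ligation (0.43, edgeR adjusted p = 0.0282). Hdc had 83 and 93 counts in Purkinje sham and 58 and 67 in Purkinje LAD. Its fall did not pass (log2 fold change -0.53, edgeR adjusted p = 0.123).

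Of 7 genes of antigen presentation by MHC class II, 4 rose after ligation in each region, and Ciita, H2-DMa and H2-DMb1 passed in neither. The log2 fold changes in Purkinje were 1.31 for H2-Aa, 1.10 for H2-Ab1, 0.84 for H2-Eb1 and 0.89 for the invariant chain gene Cd74, and in background 1.12, 0.67, 0.68 and 0.83 in the same order, all past the threshold; their interactions, between 0.06 and 0.43, did not pass. The uroplakin genes Upk3b and Upk1b, markers of the mesothelial surface of the heart, had 0 counts in all 4 Purkinje libraries, and were at least 535-fold and at least 163-fold higher in background (floor of 3 counts over the 4 Purkinje libraries). The median of the epicardium and valve list was -2.27, also with these 2 genes at their bounds. Of 14 circadian clock genes, 9 were higher in Purkinje (Per1 1.08, Per2 1.17, Per3 0.79, Nr1d1 0.70, Cry2 0.63, Arntl 0.61, Ciart 0.75, Dbp 0.45 and Tef 0.17) and 3 lower (Bhlhe41 -0.58, Clock -0.18 and Nr1d2 -0.17). Npas2 and Cry1 were not called. These are TMM-scaled values; the group was not tested as a list, and other scalings were not run for it.

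Xist, the transcript of the inactive X chromosome, was present in every library, at 34.2 CPM in Purkinje LAD replicate 2 and 387 CPM in Purkinje sham replicate 1. The 4 Y-linked genes had 1 count in all in Purkinje sham replicate 1, and 2348 counts in the background sham replicate of the same number. Male tissue was thus present in the second and not measurably in the first.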
